A study of Mus musculus with 4 samples.

How the data were processed

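The samples were 4 libraries of mouse cochlear tissue from postnatal day 7, 2 pools each of Otof heterozygous and Otof homozygous knockout animals, with both cochleas of 2 to 3 pups in each pool. Per the labels' protocols, RNA was purified on columns, had RNA integrity values above 9, and was selected with poly-T beads before random-primed cDNA synthesis. Whether the libraries kept strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart.

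The authors deposited a table of estimated counts per gene, made with Salmon against mm10 per the submitters' processing notes, within the nf-core pipeline per the labels. Versions and the gene annotation are not given in the sources used here. Gene symbols are the only identifiers in it. Between 92.4% and 92.8% of the values in a library were exactly whole numbers, and the library totals differed, as for values that were not normalised. The table held 24411 genes, 5864 of them at 0 in every library, and 27 symbols had been turned into dates. No mitochondrial-genome genes of the fixed list were in it, so that list was not tested. The authors also deposited a table of their own DESeq2 comparison, with a log2 fold change and its standard error, a Wald score, a p-value and an adjusted p-value, and the mean normalised signal per gene, per the file headers. It lists only genes past an adjusted p of 0.01 and an absolute log2 fold change of 0.5, as its values show. Its fold changes correlated at r = 1.00 over the 342 genes (rounded) with a DESeq2 fit of the same 4 libraries.

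The estimated counts were rounded to whole numbers. The main test was edgeR 4.0.16 (quasi-likelihood F test, trimmed mean of M-values scaling, filterByExpr, in R 4.3.3), with genotype as the only term and Benjamini-Hochberg adjustment over the 15359 genes tested. Fold changes are homozygous over heterozygous with the standard error implied by the F statistic. CPM are counts per 1000000 on scaled library sizes. Every difference rests on 2 pools against 2, so a rank or permutation test of a single gene could not reach 0.05 and none was run. DESeq2 1.42.0 (Wald test, default settings) was the other test listed beforehand and is the tool the submitters name. The verbs rose and fell are used for genes with a DESeq2 adjusted p under 0.05. Before the data were examined, 34 gene lists were fixed, from K+ channel families to markers of the cell types that a dissected cochlea can hold, and 33 with at least 3 genes tested went into camera (limma 3.58.1, inter-gene correlation 0.01), adjusted over the 33 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera's test rests on the 2 residual degrees of freedom of the fit, which leaves it little power. A call lost there is not by itself evidence that the genes of a list are correlated. Some genes are held by more than 1 list.

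The genes to name were also set by a rule before the data were examined. It took Otof, the HCN genes, Kv genes with an unadjusted p under 0.05, and 10 genes per direction by fold change among those past edgeR's adjusted p. As none passed, the 10 of smallest p per direction whose pools did not overlap were taken, without predicted gene models. It also took up to 4 genes of smallest p from each called list, up to 2 from other lists, and the 5 highest and 5 lowest fold changes of the authors' table. Some genes that the rule takes are not reported here. Positions come from GENCODE M21 on GRCm38, which is the build the submitters call mm10. The annotation the authors used may differ.

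The edgeR, DESeq2 and camera steps were tested on simulated data for this comparison, with the real means, dispersions and library sizes and 200 changed genes. Of 100 genes changed 2-fold edgeR recovered 73% (15204 genes tested) and DESeq2 88% (15359 genes tested), and of 100 changed 4-fold each recovered all. edgeR made 18 false calls there and DESeq2 58. The real pools gave edgeR 2.86 prior degrees of freedom beside 2 residual ones, against 9.43 in the simulation, which means that the variance differed more between real genes than between simulated ones. The simulation also held no differences shared by many genes of a pool, so its recovered shares and false calls do not carry over to the real pools. Replicates of a genotype differed by more than sampling noise (chi-square per degree of freedom 29.8 and 49.0), unlike repeat runs of 1 library, and each counted as a replicate per the labels.

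Settings varied by a list made before the data were examined were other size factors (RLE, upper quartile), no filter or a stricter filter of at least 1 CPM in at least 2 pools, DESeq2, a replicate block, the 2 other list tests, and leaving out each pool in turn. With a pool left out, the lone pool of that genotype is assumed to vary like the other genotype. Chosen after seeing the data were robust variance shrinkage, bias-adjusted deviances, limma voom, DESeq2 with the block or without each pool, camera with the block and an estimated correlation, the fit without sex-linked genes, and lists without shared genes.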

Results

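Messenger RNA was sequenced from cochlear tissue of mice at postnatal day 7. The animals were heterozygous or homozygous for a knockout of Otof, the gene of otoferlin, a calcium sensor that inner hair cells need to release glutamate onto spiral ganglion neurons. Each library came from a pool of both cochleas of 2 to 3 pups, and there were 2 pools per genotype, 4 libraries in all. The heterozygous libraries held 36060278 and 32453536 estimated counts and the homozygous libraries 38090724 and 31509350. At this depth 3 counts, the limit that a count of 0 allows, correspond to 0.0776 to 0.0944 counts per 1000000 (CPM), which covers counting error only. Across the 15359 genes tested, log2 CPM correlated at r = 0.982 between the heterozygous pools and at r = 0.980 between the homozygous pools, over genes, which are not independent replicates. The pools differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, had 5771 and 6733 counts in the heterozygous pools, 2 counts in homozygous replicate 1 and 19085 counts in homozygous replicate 2. The Y-linked gene Ddx3y had 2700 and 1872 counts in the heterozygous pools, 3878 in homozygous replicate 1 and 0 in homozygous replicate 2.

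Otof itself, on chromosome 5 (30367062 to 30461932, minus strand, GRCm38), was lower in both homozygous pools. It had 86 and 83 counts in heterozygous replicates 1 and 2, and 5 and 9 counts in homozygous replicates 1 and 2. Its level was 2.51 ± 0.14 CPM in heterozygous and 0.205 ± 0.11 CPM in homozygous pools (mean ± SD, n = 2). The log2 fold change was -3.62 ± 0.46 (SE), which was an adjusted p of 0.116 by edgeR's quasi-likelihood test and 9.82e-06 by DESeq2. The order of the 4 libraries by Otof thus matched their genotype labels.

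The first comparison asked which genes differed between homozygous and heterozygous cochleas. The lower genes of smallest p included Ache, Pmp2, Rcan2 and Hapln1. Ache, acetylcholinesterase, was 60.7 ± 1.0 CPM in heterozygous and 20.9 ± 0.86 CPM in homozygous pools (mean ± SD, n = 2). Pmp2, a lipid-binding protein of peripheral myelin, went from 84.7 ± 9.3 to 24.8 ± 0.85 CPM, and Rcan2, a calcineurin regulator, from 164 ± 9.6 to 50.7 ± 7.1 CPM. Hapln1, a link protein of hyaluronan matrix, went from 97.1 ± 14 to 33.5 ± 0.039 CPM. AI506816, a noncoding transcript 6.71 Mb from Otof on chromosome 5, had 513 and 422 counts in the heterozygous pools and 5 and 11 in the homozygous pools. The other lower genes taken by smallest p were Zmat4 (log2 fold change -2.42 ± 0.18), Flt3 (-2.57 ± 0.20), Lgi2 (-1.64 ± 0.13), Sec14l5 (-1.40 ± 0.11) and Ddn (-1.61 ± 0.13, dendrin). Among genes higher in the homozygous pools were Postn, the matrix protein periostin (0.72 ± 0.07), Ppp1r1b (0.94 ± 0.09), Necab1, a neuronal calcium-binding protein (1.34 ± 0.14), Matn2 (0.99 ± 0.10), Prss23 (0.72 ± 0.08) and S1pr3, a sphingosine phosphate receptor (0.83 ± 0.10). The same rule took Vwa1 (0.64 ± 0.07), St8sia2, a polysialyltransferase (1.47 ± 0.17), and Itgb3, an integrin subunit (0.89 ± 0.11). It also took Oaz1-ps, a processed pseudogene with 0 and 0 counts in the heterozygous pools and 1652 and 619 in the homozygous pools, at least 204-fold higher against a floor of 3 counts per library. Its reads can be shared with its parent gene Oaz1, so this value is uncertain.

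All of these genes passed DESeq2 at an adjusted p of 0.05, and none passed edgeR's quasi-likelihood test, the test fixed for this comparison. edgeR called 0 of 15359 genes, with a smallest adjusted p of 0.101, while 2038 genes had an unadjusted p under 0.05, of which 670 were higher and 1368 lower. DESeq2 called 664 genes, 158 that rose and 506 that fell, and in all 664 the pools of the 2 genotypes did not overlap in CPM. Of all genes tested, 46.1% did not overlap, against 33.3% by chance. The DESeq2 count was 223, 169, 686 and 307 without heterozygous replicates 1 and 2 and homozygous replicates 1 and 2 in turn, and edgeR called 60 genes without homozygous replicate 1. In counts simulated with no difference DESeq2 still called 37 genes and edgeR 1. The simulated libraries were drawn independently, and their variance differed less between genes than in the real pools. These counts are thus not a rate of false calls for the real pools.

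The series title names K+ and HCN channels, so the next comparison asked how these genes differed. Hcn4 (chromosome 9, 58823412 to 58863175), a channel of the hyperpolarisation-activated current, fell by DESeq2 from 21.1 ± 1.4 CPM in heterozygous to 10.2 ± 1.4 CPM in homozygous pools (mean ± SD, n = 2). Hcn2, with a log2 fold change of -0.73 ± 0.29, and Hcn3, with 0.08 ± 0.25, did not pass either test. The Kv channels, the voltage-gated K+ channels, went both ways, with 3 that rose and 6 that fell by DESeq2 among 36 tested. Kcnc1 and Kcnc2, which carry fast high-threshold K+ currents, fell, and Kcnc4 of the same family rose.

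Kcnc1 was 178 ± 17 CPM in heterozygous and 108 ± 22 CPM in homozygous pools (mean ± SD, n = 2). The log2 fold changes were -0.72 ± 0.16 for Kcnc1 and -1.56 ± 0.37 for Kcnc2. Also among those that fell were Kcna2, a low-threshold channel of axons (-0.64 ± 0.14), Kcnd2, an A-type channel (-1.62 ± 0.35), and Kcns3, a modulatory subunit (-1.02 ± 0.18). The 3 that rose were Kcnc4 (0.92 ± 0.16), Kcna6 (0.80 ± 0.15) and Kcnh8 (0.86 ± 0.20). Others had an unadjusted edgeR p under 0.05 without passing DESeq2, among them Kcnd3 (-0.48 ± 0.12), Kcnq3 (-0.70 ± 0.18), Kcns1 (-0.51 ± 0.16) and Kcnh6 (1.13 ± 0.29).

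By edgeR 0 Kv and 0 HCN genes passed when adjusted over all genes, while adjusted over the list alone 12 Kv genes passed, 4 higher and 8 lower, and Hcn4 passed as lower in the HCN list. As a list, the HCN channels were called lower by camera (adjusted p = 0.0197), with an adjusted p of 0.529 with an estimated correlation. That call was lost without heterozygous replicate 1 (camera's adjusted p = 0.0681) and without homozygous replicate 2 (0.0762). The Kv list was not called by camera (adjusted p = 0.112, median log2 fold change -0.33), with an adjusted p of 0.562 with an estimated correlation. It was called lower with a replicate block (camera's adjusted p = 0.0427), and the labels do not say that the replicate numbers pair the pools. With the block and an estimated correlation it was not called (0.743). That test has even fewer residual degrees of freedom than without the block, so it has little power and does not decide the question. In the same homozygous pools 19 of 38 neuronal markers fell by DESeq2, and central glia markers lay below the heterozygous mean by a median log2 difference of -0.34 in replicate 1 and -2.23 in replicate 2.

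**Figure D1:**
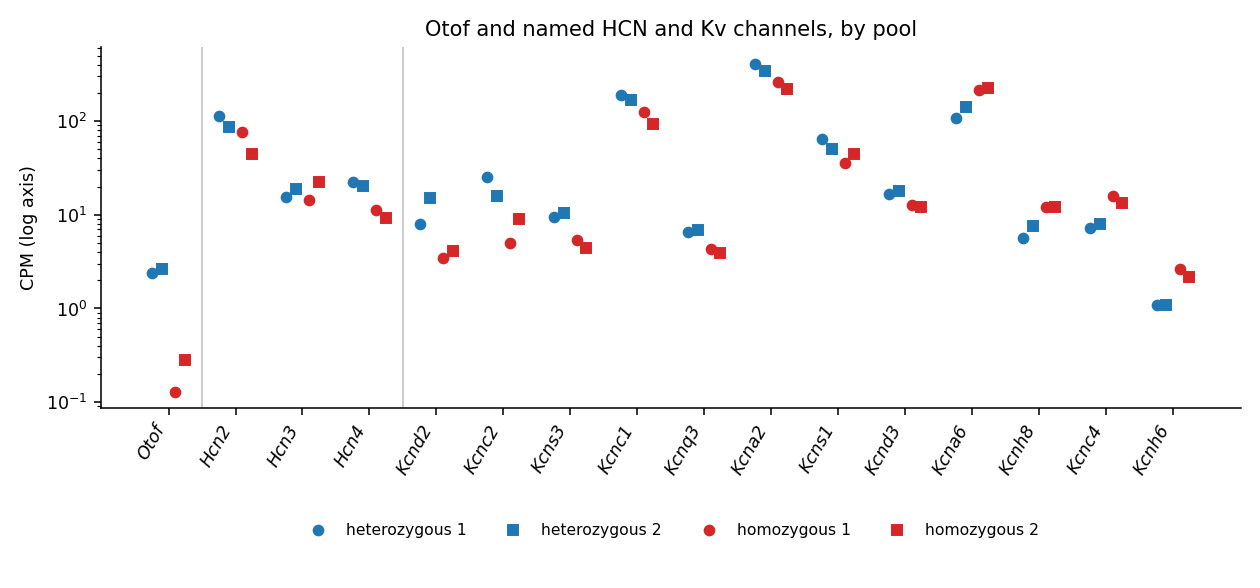
CPM (log axis) of Otof, Hcn2, Hcn3, Hcn4 and the Kv genes named in the text in each of the 4 pools (blue, heterozygous; red, homozygous; circle, replicate 1; square, replicate 2). Hcn4 lay at 21.1 CPM on average in heterozygous and 10.2 CPM in homozygous pools, and the Hcn3 points of the genotypes overlapped.

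Further classes of K+ channel genes were called lower as lists. Of the inward rectifier and two-pore K+ channels, which set resting conductance, 3 of 22 fell by DESeq2 and 0 rose. They were Kcnk3 (-2.40 ± 0.28), whose midpoint lies 0.192 Mb from that of Otof, Kcnj16 (-1.40 ± 0.26) and Kcnj11 (-0.75 ± 0.16), and Kcnk12 had -2.07 ± 0.53 without passing. Among the 16 genes listed as auxiliary subunits of Kv and HCN channels, Lgi2 and Kcnip3 fell, while Lgi1 rose. Kcnip3, a calcium-binding partner of A-type channels, had -2.18 ± 0.20 and Lgi1 1.01 ± 0.16. Lgi1 and Lgi2 are secreted proteins and not subunits of a channel itself. Camera gave adjusted p = 1.51e-05 for the inward rectifier and two-pore list and 0.00106 for the auxiliary list, and each had an adjusted p of 0.529 with an estimated correlation. Lists that camera did not call were the voltage-gated Na+ channels (adjusted p = 0.124), of which Scn1a (-0.58 ± 0.12) and Scn8a (-0.90 ± 0.19) fell by DESeq2, and the voltage-gated Ca2+ channels (0.175), of which Cacna1d (0.46 ± 0.08) and Cacna1e (0.59 ± 0.11) rose. Of the calcium- and sodium-activated K+ channels 0 of 10 passed DESeq2, and camera gave an adjusted p of 0.885.

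Neuronal genes were lower in the homozygous pools. Of 38 spiral ganglion and pan-neuronal markers, 19 fell and 1 rose by DESeq2. Slc17a6, a vesicular glutamate transporter, was 103 ± 11 CPM in heterozygous and 35.2 ± 6.6 CPM in homozygous pools (mean ± SD, n = 2). Snap25, a protein of vesicle fusion, had a log2 fold change of -0.84 ± 0.13, Eno2 of -0.77 ± 0.10, Thy1 of -0.75 ± 0.09 and Ina, a neurofilament protein, of -0.53 ± 0.08. The gene that rose was Gata3, a transcription factor of spiral ganglion neurons, at 27.5 ± 6.5 against 59.7 ± 4.2 CPM. Camera called the list lower (adjusted p = 1.54e-12), with an adjusted p of 0.529 with an estimated correlation.

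Type II spiral ganglion neuron markers were called higher by camera (adjusted p = 0.00172, and 0.562 with an estimated correlation), with Gata3 as the only member of 11 past DESeq2. Calca (1.74 ± 0.65) did not pass, and the call was lost without homozygous replicate 1 (adjusted p = 0.0936). Type I subtype markers were not called (camera's adjusted p = 0.152), although Pou4f1, a transcription factor that marks a subtype, fell by DESeq2 (-1.34 ± 0.26). Of 37 glutamate receptor and postsynaptic genes, 3 fell by DESeq2, among them Cacng5 (-1.07 ± 0.11) and Grm5 (-3.13 ± 0.56). That list was called lower by camera (adjusted p = 0.0256, and 0.664 with an estimated correlation), and not without heterozygous replicate 2 (0.509) or homozygous replicate 2 (0.176). Camera did not call the ribbon synapse genes (adjusted p = 0.169), the activity-regulated genes (0.169) or the neurotrophin and neuregulin genes (0.391). Of the activity-regulated genes, Egr3 (0.77 ± 0.12) and Jun (0.42 ± 0.07) were among 4 that rose by DESeq2, and 2 fell.

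Many myelin genes were lower in the homozygous pools. Of 33 Schwann and myelin genes, 14 fell and 0 rose by DESeq2. Pmp22, a protein of compact myelin, had a log2 fold change of -0.86 ± 0.12, Drp2 of -1.03 ± 0.15 and Pmp2 of -1.77 ± 0.11. Genes of central glia, oligodendrocytes and astrocytes, were also lower, with 2 of 14 past DESeq2, Slc1a2 (-1.13 ± 0.25) and Aldh1l1 (-1.64 ± 0.44). The 2 homozygous pools differed in these genes: relative to the heterozygous mean, the median log2 difference was -0.34 in homozygous replicate 1 and -2.23 in homozygous replicate 2. Camera called both lists lower, at adjusted p = 1.52e-15 for the Schwann and myelin genes and 2.09e-06 for central glia, with adjusted p of 0.529 and 0.603 with an estimated correlation.

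**Figure D2:**
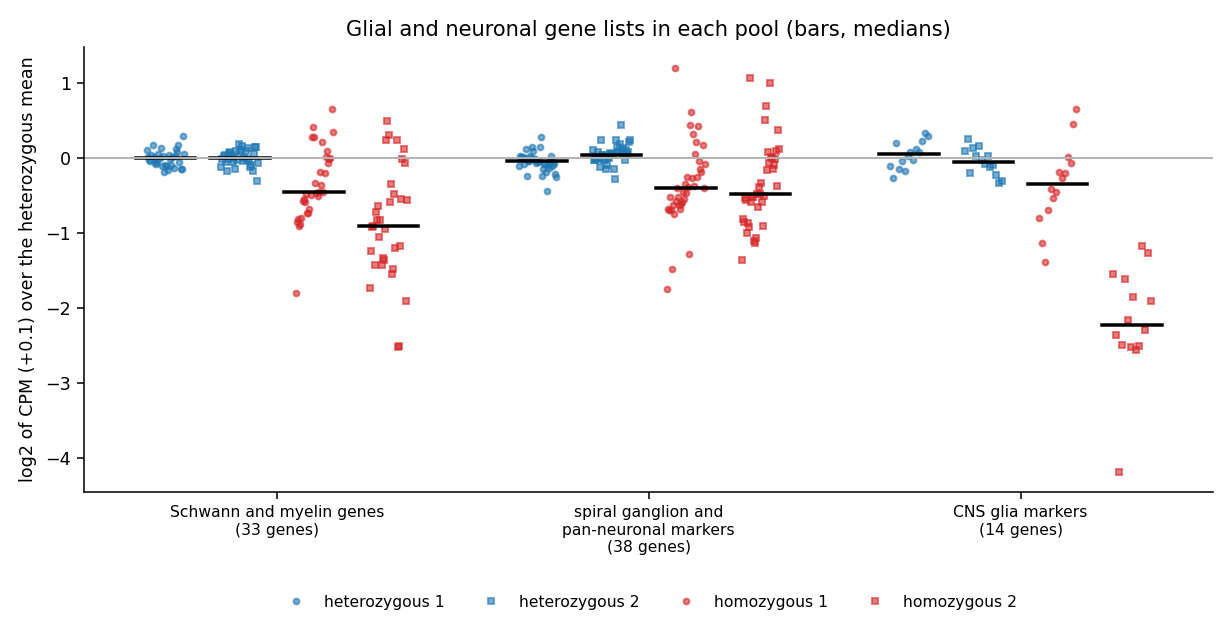
Log2 of CPM plus 0.1, relative to the heterozygous mean, of each gene in 3 of the fixed lists in the 4 pools (points, genes; bars, medians; blue, heterozygous; red, homozygous). In homozygous replicates 1 and 2 the medians were -0.45 and -0.90 for the Schwann and myelin genes, -0.40 and -0.48 for the neuronal markers and -0.34 and -2.23 for the central glia markers.

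Proliferation genes were higher in the homozygous pools. All 30 cell cycle genes had a fold change above 0, and 18 had an unadjusted edgeR p under 0.05, but only Aurkb (0.68 ± 0.15) passed DESeq2. Mcm7 (0.41 ± 0.09), Ccnb2 (0.62 ± 0.14) and Top2a (0.46 ± 0.11) did not. Connective tissue lists were higher too. Among 23 fibroblast genes, Postn, Fbn2 (0.38 ± 0.08) and Dcn, decorin (0.53 ± 0.12), were among 4 that rose by DESeq2 and Thy1, also expressed by neurons, fell. Among 27 bone and cartilage genes Col1a2 (0.45 ± 0.15) rose and Hapln1 fell. By camera, the adjusted p was 1.16e-12 for cell cycle, 5.22e-05 for fibroblast and 0.00569 for bone and cartilage genes, and 0.529, 0.593 and 0.671 with an estimated correlation. Without heterozygous replicate 2 the fibroblast and bone calls were lost, and the direction of the bone and cartilage list turned to lower. The interferon-response genes were called higher (camera's adjusted p = 0.0249, and 0.603 with an estimated correlation) with 0 of 28 past DESeq2, and that call was lost without heterozygous replicate 2 (0.258) or homozygous replicate 1 (0.126).

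Hair cell and skeletal muscle genes were called lower. Of 22 hair cell markers, 3 fell and 1 rose by DESeq2. Cabp1, a calcium-binding protein, had -1.05 ± 0.09, Pcdh15, of the tip links, -1.19 ± 0.26, and Espn, an actin bundler of stereocilia, 0.55 ± 0.12. Of 21 skeletal muscle genes 3 fell, Ryr1 (-1.81 ± 0.20), Xirp1 (-2.47 ± 0.30) and Pvalb (-0.74 ± 0.11), of which Pvalb is also a neuronal gene. Camera's adjusted p was 0.012 for hair cell and 0.0113 for muscle genes, and 0.529 and 0.562 with an estimated correlation. Without heterozygous replicate 1 both calls were lost (adjusted p = 0.0858 and 0.297), and the hair cell call also without homozygous replicate 1 (0.105).

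Camera did not call the lists of supporting cells (adjusted p = 0.544), stria vascularis and spiral ligament (0.391), osteoclasts (0.169), erythroid cells (0.169), neutrophils and marrow myeloid cells (0.801), macrophages (0.504), lymphoid cells (0.124) or endothelium and pericytes (0.303). The same held for heat shock (adjusted p = 0.576), ribosomal protein (0.124) and Y-linked genes (0.153). In all, camera called 14 of the 33 lists tested, 5 higher and 9 lower. With an estimated correlation it called 0. Among the called lists, the estimates lay below the preset 0.01 for the HCN (-0.013), auxiliary (-0.0074) and hair cell (-0.042) lists and above it for all others. Examples are 0.29 for cell cycle, 0.35 for Schwann and myelin and 0.93 for central glia genes. Where the genes of a list are correlated above the preset, camera's p with the preset is too small. The lost calls thus reflect the 2 residual degrees of freedom as well as any correlation between genes. By fry, which asks whether a list moves on balance one way, 0 lists were called, with a smallest adjusted p of 0.0762. fry's mixed test, of change in either direction, called 13.

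**Figure D3:**
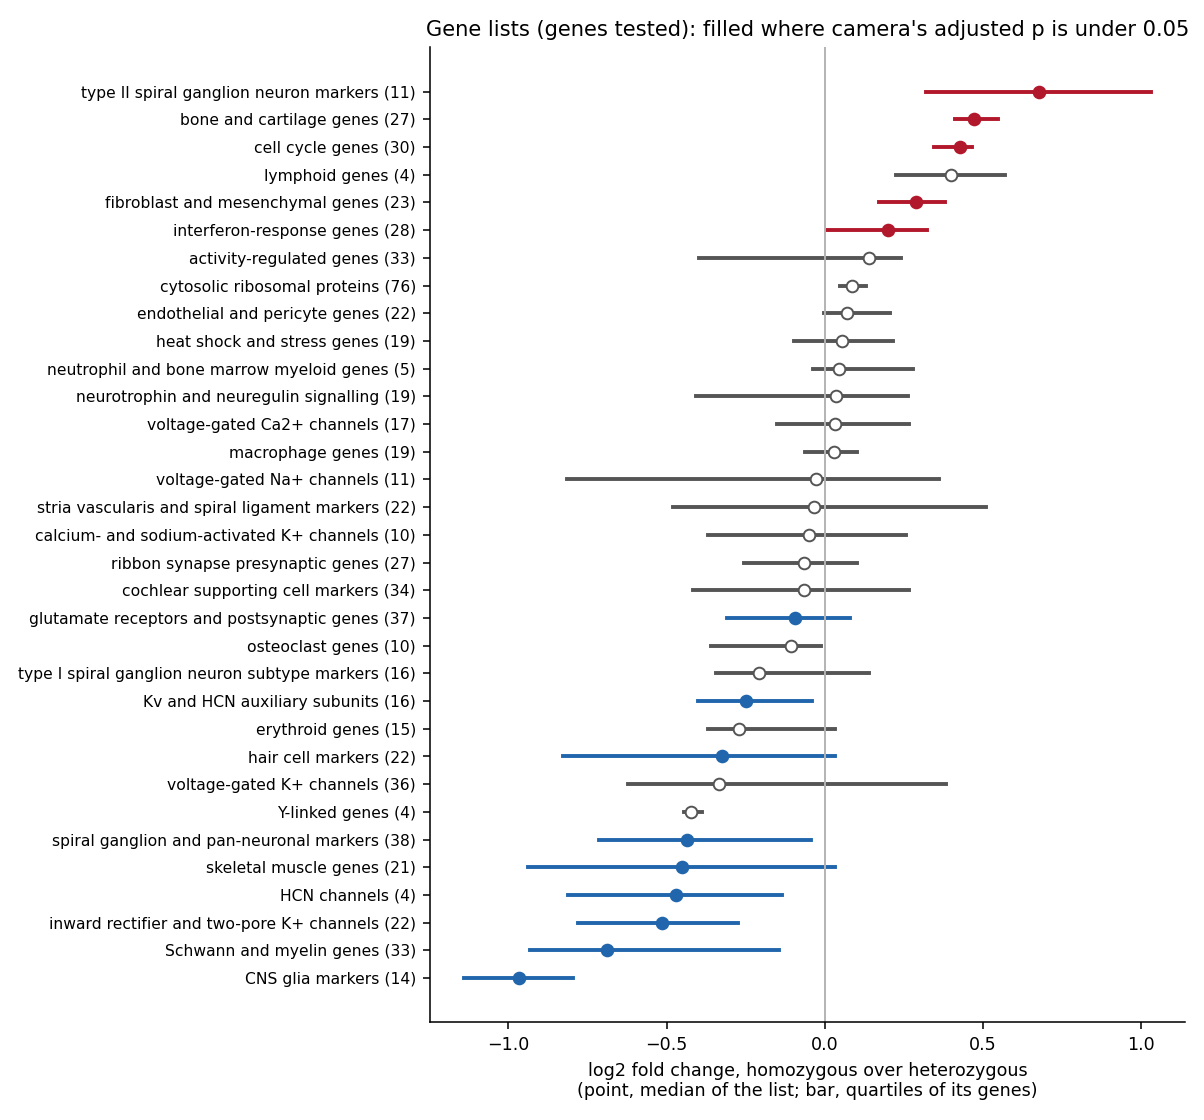
Log2 fold change (homozygous over heterozygous) of the 33 gene lists tested, with the median of each list (point) and the quartiles of its genes (bar); filled points mark lists with a camera adjusted p under 0.05 (red, higher; blue, lower). The medians ran from -0.97 for central glia to 0.68 for type II neuron markers.

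The last comparison set the fits beside the authors' deposited table of changed genes. The authors' deposited table listed 343 genes, 72 higher and 271 lower, each with an adjusted p under 0.01 (largest 0.00982) and an absolute log2 fold change over 0.5 (smallest 0.50). Its lowest values were for AI506816 (-5.91), Hs3st2 (-4.10), Hapln4 (-3.93), Lsmem1 (-3.68) and Otof (-3.63). Its highest values were for Hrk, a BH3-only gene of neuronal apoptosis (2.13), Shisa6 (1.75), Ces2g (1.52) and St8sia2 (1.48), again in the authors' deposited table. Of the 343 genes, 342 were found by name among the counts. All 342 had the same sign in the edgeR fit and an unadjusted p under 0.05 there, and 0 passed edgeR's adjusted p of 0.05. A DESeq2 fit of the 4 libraries gave 345 genes past both of those limits, 336 of them listed by the authors. The name of the table speaks of removed outliers without saying which, and the differences from this fit were not explained. Its fold changes lay close to those of the 4 libraries, so it is not independent evidence.

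Some of the largest falls lay close to Otof. Within 20 Mb of it, 6 other genes passed DESeq2 with a log2 fold change below -2, and those outside AI506816 and Kcnk3 were chosen for naming after their values were seen. They were Trim54 (31116712 to 31137630) at -3.06 ± 0.58, Otop1 (38275972 to 38304217), a proton channel, at -2.47 ± 0.28, and Fam184b (45529705 to 45639614) at -3.19 ± 0.31. The last was 9630001P10Rik (45638699 to 45645469) at -4.36 ± 0.65, which is annotated antisense to Fam184b and overlaps the start of that gene, so reads from the shared stretch may not be told apart.

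**Figure D4:**
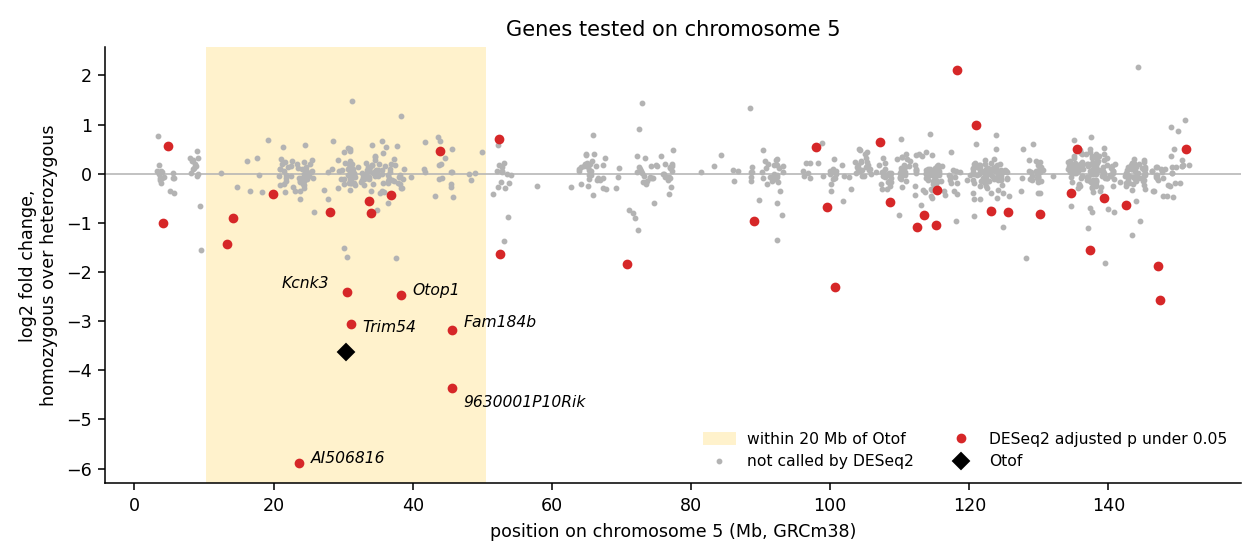
Log2 fold change (homozygous over heterozygous) of genes tested on chromosome 5 against their midpoint in Mb (GRCm38), with Otof as a diamond, genes past DESeq2's adjusted p of 0.05 in red, and the 20 Mb on either side of Otof shaded. Besides Otof, 6 genes in the shaded region changed by more than 2 on the log2 scale, AI506816, Kcnk3, Trim54, Otop1, Fam184b and 9630001P10Rik, all of them lower.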

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

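No alternative turned the Otof fold change or the direction of the HCN or Kv list. Every size factor and both filters left edgeR's count of 0 genes, as did robust shrinkage, bias-adjusted deviances, limma voom and leaving out sex-linked genes, all chosen after seeing the data. DESeq2 moved it to 664 genes. edgeR's range without 1 pool was 0 to 60, and the lone pool is then assumed to vary like the other genotype. The DESeq2 count, 664, ranged from 169 to 686 without 1 pool. Of the calls made with all pools, 140 were called again without heterozygous replicate 2. The cause of these moves was not tested.

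The labels do not say whether the replicate numbers pair the pools. With 2 pairs, deviations from the genotype mean correlated at r = 0.31 across genes, which are not independent. Pools of the same number thus leaned the same way, a difference that the main fit leaves in its residual. A replicate block moved edgeR's count to 495 genes, 132 higher and 363 lower, and DESeq2's to 600, and the Otof fold change then passed edgeR (log2 -3.64, adjusted p = 0.0266). With the block, camera also called the Kv (adjusted p = 0.0427) and voltage-gated Na+ (0.0222) lists lower, while with the block and an estimated correlation, chosen after seeing the data, it called 0 lists (0.743 for the Kv, Na+ and HCN lists). The block leaves fewer residual degrees of freedom than the main fit, so that last test has little power against any list. Under DESeq2 the Otof fold change passed at -3.63, and with the block at -3.69. A split by replicate number in place of genotype gave 152 DESeq2 calls and the remaining split 1, so the pools also differ along their numbers.

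Without 1 pool, the Otof fold change was -4.23 to -3.16, the adjusted p of camera 0.00495 to 0.0762 for the HCN list and 0.0982 to 0.197 for the Kv list, and the lists called 14 to 17. The authors' genes of matching sign stayed at 342, which their pools, not overlapping in CPM, fix beforehand. The HCN call was lost with an estimated correlation (adjusted p = 0.529) and with fry (0.24), and the number of lists called fell to 0 with either. Of the 14 called lists, 6 stayed called without any 1 pool, which were cell cycle, Schwann and myelin, central glia, neuronal, inward rectifier and two-pore, and auxiliary subunit genes, and 8 lost the call without at least 1. The bone and cartilage list turned to lower without heterozygous replicate 2, uncalled (adjusted p = 0.376). Of the lists not called, 4 were called both ways without 1 pool: osteoclast (higher, 2.12e-08, without heterozygous replicate 1; lower, 0.000734, without heterozygous replicate 2), endothelial (3.06e-07 and 0.00527, likewise), ribosomal (higher, 2.95e-18, without homozygous replicate 1; lower, 1.51e-07, without homozygous replicate 2) and Y-linked genes (lower, 7.50e-22, and higher, 0.000266, likewise). Another 5 were called 1 way without at least 1 pool: lymphoid (higher in 3 of the 4 fits, lowest 0.00339), macrophage (higher, 0.000466), erythroid (lower, 0.0227 and 0.046), type I neuron (lower, 0.00893) and ribbon synapse genes (lower, 0.039). With genes of more than 1 list left out, 12 lists were called, and the type II (adjusted p = 0.198) and hair cell (0.0965) calls were lost.

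Among single genes near 0, signs turned without 1 pool: Hcn3 ranged from -0.26 to 0.35, Sox10 from -0.10 to 0.20, Stmn2 from -0.26 to 0.018, Uchl1 from -0.18 to 0.025 and Isl1 from -0.17 to 0.086. Xist ranged from -11.7 to 1.66 and Ddx3y from -14.1 to 0.58, and Xist was -2.32 with the block, -4.98 by DESeq2 with the block and -5.44 by limma voom. No other named gene turned. Depth limits Otof, at 5 and 9 counts in the homozygous pools.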

Other observations

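The sterol, net and GABA gene sets and the tests of explanations in this part were chosen after the values were seen. So were the genes named here that the naming rule did not take. The DESeq2 fit and the Schwann, neuronal and central glia lists were fixed before. Sterol synthesis genes were lower together: all 22 tested had a fold change below 0, and 17 fell by DESeq2 and 0 rose. Hmgcs1, an early enzyme of the mevalonate pathway, had a log2 fold change of -1.09 ± 0.21 (SE, n = 2 pools per genotype), Idi1 -1.10 ± 0.16 and Cyp51 -0.99 ± 0.17. The median was -0.60 in homozygous replicate 1 and -0.89 in homozygous replicate 2, relative to the heterozygous mean, where the Schwann and myelin genes had -0.45 and -0.90 and the central glia markers -0.34 and -2.23. Camera gave an adjusted p of 8.03e-34 over the 3 sets chosen this way, and an adjusted p of 0.128 with an estimated correlation. As the sets were chosen from these same values, neither p-value is evidence for a change.

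Of 13 perineuronal net genes, 6 fell by DESeq2 and 0 rose. Hapln4, a link protein of nets around neurons, was 69.4 ± 19 CPM in heterozygous and 4.52 ± 2.2 CPM in homozygous pools (mean ± SD, n = 2), and Ncan, a matrix proteoglycan, had a log2 fold change of -1.47 ± 0.25. Acan had 0.54 ± 0.27 and did not pass. The net genes had medians of -0.75 in homozygous replicate 1 and -1.29 in homozygous replicate 2, relative to the heterozygous mean, and the GABA and glycine genes -0.60 and -1.30, where the central glia markers had -0.34 and -2.23. Gene by gene, the gap (homozygous replicate 2 minus replicate 1) had a median of -0.015 (lower quartile -1.03) for the net genes. It was -0.048 (lower quartile -0.80) for the GABA and glycine genes and -1.76 for central glia. Among 20 GABA and glycine receptor and transport genes 5 fell and 0 rose. Slc12a5, the neuronal K-Cl cotransporter, was uneven between the heterozygous pools, at 12.3 and 26.7 CPM, and at 4.32 and 4.24 CPM in the homozygous pools. Camera gave adjusted p of 5.8e-13 for the net genes and 1.64e-11 for the GABA and glycine genes, and adjusted p of 0.0594 and 0.128 with an estimated correlation. Both sets were chosen after the values were seen, so these p-values are not evidence for a change either.

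Of the 33 Schwann and myelin genes, 14 fell by DESeq2. Less central nerve tissue, with its oligodendrocytes, is argued against as the whole cause by the gap between the homozygous pools (replicate 2 minus replicate 1, log2), which had a median of -0.26 (lower quartile -0.60) over the 29 Schwann and myelin genes outside the central glia list, against -1.76 (upper quartile -1.33) for the central glia markers. Fewer Schwann cells of every kind would lower all 33 genes alike only if no other cells expressed them. At the best single fold change 12 of them lay outside their DESeq2 95% interval, where 1.65 are expected by chance. Sox10 (0.04 ± 0.14) and Erbb3 (0.30 ± 0.10) were among those above it. Some of the 33 genes are also central glia markers, and sources outside Schwann cells were not measured. Fewer Schwann cells thus stay open as part of the cause. The sex of the pups is argued against, since the homozygous pools lay on opposite sides of the heterozygous pools in Xist and Ddx3y counts, while the 33 genes had medians of -0.45 and -0.90, both below the heterozygous mean. Fewer myelinating cells among the Schwann cells, lower expression of myelin genes within them, with the genotype, and a difference in maturity between litters, which the design does not separate from genotype, were not tested and stay open.

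Of the 38 neuronal markers, whose median log2 fold change was -0.43, 19 fell by DESeq2. Less central nervous tissue, with neurons and glia in step, is argued against as the whole cause by the gap between the homozygous pools. Its median was -0.017 (lower quartile -0.20) over the 38 genes against -1.76 for the central glia markers. The GABA and glycine genes were lower in both homozygous pools with a median gap of -0.048. A loss of central neurons out of step with central glia was not tested and stays open. Fewer neurons of every kind would lower all 38 alike only if no other cells expressed them. At the best single fold change 15 lay outside their DESeq2 95% interval, where 1.90 are expected by chance. Slc17a6 (-1.55 ± 0.16) lay below it and Stmn2 (-0.13 ± 0.15), Uchl1 (-0.08 ± 0.12) and Isl1 (-0.04 ± 0.12) above it. Sources outside neurons were not measured, so fewer neurons stay open as part of the cause. The sex of the pups is argued against by medians of -0.40 and -0.48 in homozygous replicates 1 and 2. Fewer neurons of 1 kind, and lower expression of some genes per neuron, with the genotype or with the maturity of the litters, were not tested and stay open.

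Large falls were dense around Otof on chromosome 5. Within 20 Mb of Otof, which was itself left out, 6 of 219 genes tested (2.74%) passed DESeq2 with an absolute log2 fold change over 2, against 43 of 14509 elsewhere (0.296%; Fisher's exact test, two-sided, p = 8.28e-05; at a limit of 1, 7 against 164, p = 0.0141), and of 14423 windows of the same width at other genes 0 held as many, with at most 3. Variants or regulatory changes carried with the Otof allele may thus account for part of this excess. The test weighs the number of falls and cannot tell the cause for any 1 gene among AI506816, Kcnk3, Trim54, Otop1 and Fam184b. The sixth, 9630001P10Rik, lies antisense to Fam184b and overlaps the start of that gene, so reads from the shared stretch may not be told apart, and neighbouring genes are not independent. A direct effect of the loss of otoferlin on these genes was not tested and stays open. The 43 genes elsewhere lie outside the 20 Mb window, and whether variants carried with the Otof allele reach any of them was not tested. They include Flt3 (147330741 to 147400489) at -2.57 ± 0.20 and Hrk (118164648 to 118189478) at 2.12 ± 0.30, which also lie on chromosome 5.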
